A study of Mus musculus with 6 samples.

How the data were processed

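RNA of 6 mouse T cell cultures was measured on Affymetrix GeneChip arrays, 3 arrays from cultures with glutamine and 3 from cultures without it. Per the labels' protocols, naive CD4 T cells were sorted by flow cytometry, stimulated through CD3 and CD28 for 3 days and cultured with 10% fetal bovine serum, IL-6 and IL-23 at 20 ng/ml each, TGF-beta at 1.25 ng/ml, and antibodies at 10 ug/ml that block IFN-gamma, IL-4 and IL-12. The deposited values are log2 expression levels per array row, which the authors made with RMA in the Transcriptome Analysis Console 4.0, per the submitters' processing notes. RMA corrects the background, normalizes the arrays and summarises the probes of a row. The options, the array annotation and the genome build that the authors used are not given in the sources used here. The 6 columns were used as deposited and no column of another sample was present (0 such columns).

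The array medians were not equal, and each array held values above 16, the log2 range of a 16-bit scanner. The deposited scale may therefore have been stretched or shifted by a step that the sources do not name, so changes are given as log2 differences on the deposited scale and not as folds. No coordinates are given. Gene names came from the platform annotation, with symbols updated through the RefSeq gene table of GRCm38.p6. Of 65956 rows, 31258 named 1 gene, 1492 named several and 33206 were unnamed here. The symbols of 1135 rows were updated, and 654 rows listing synonyms of 1 gene were counted as naming that gene. Where a symbol had more than 1 row, as 441 symbols did, the row with the highest mean over the 6 arrays was used. This left 30702 genes, with no filter on dim ones. Of the 997 entries in the fixed gene lists, 892 were measured. Foxp3, Gata3 and Glul are not analysed here because their rows name several genes.

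Each gene was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 for the difference between cultures without and with glutamine, with no covariate. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Values are means ± SD over n = 3 arrays per group, and a change is the mean without glutamine minus the mean with it. The 41 gene lists were tested with limma's camera, which asks whether the members of a list shift against all other genes, at its preset inter-gene correlation of 0.01, adjusted over the lists. A list needed 5 measured members. The lists covered T helper programmes, T cell identity and activation, amino acid, nucleotide, lipid and energy metabolism, growth and stress responses, and markers of other cell types. Some lists share genes: 9 genes stand in both the hypoxia and the glycolysis list, 8 in both the ATF4 and the serine list, and 6 in both the TH1 and the pathogenic TH17 list.

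The design, the lists and the rule for naming genes were set before the data were examined. The rule takes the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, leaving out predicted genes and small RNAs. It also takes a fixed set of genes whatever their values, and up to 4 members per list with the largest changes past the threshold, or the 2 brightest members where fewer than 2 passed. Genes the rule takes are not all printed: most whose call ended when 1 array was left out are omitted. Genes outside this rule are said to have been chosen after their values were seen.

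The gene test was tested on simulated data with the mean and spread of the 30702 genes and 200 changed genes, 50 of each size. It recovered 28% of the genes changed by 0.5 log2, 84% of those changed by 1, 94% of those changed by 2 and 100% of those changed by 3, with 9 false calls. Far fewer genes changed there than were called in the real data (22.3% of those tested). The adjustment depends on that share, so these rates do not give the recovery in the real data. In 40 simulated lists of 25 genes, the list test called 4 of the 4 lists shifted by 0.5 log2 and 0 of the other lists; its simulated genes were independent of each other, which real genes are not.

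Alternatives were quantile normalization, centring each array on its median, genes above the median level, all rows, the mean over the rows of a symbol, eBayes with trend and robust, array weights, adjusted p under 0.01, adjusted or unadjusted p under 0.05 with a 2-fold change, an unmoderated statistic, the replicate number as a block, and leaving out each array. For the lists, an estimated inter-gene correlation, fry and camera on ranks were added. The alternatives of protein coding genes only and the hypoxia and glycolysis lists without their shared genes, were chosen after seeing the data. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.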

Results

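The arrays compared mouse TH17-skewed T cells, helper cells driven toward IL-17 secretion, after 3 days of culture with or without glutamine, an amino acid that supplies carbon to the TCA cycle and nitrogen to nucleotides. The comparison asks how the absence of glutamine changes the transcripts of these cells. Each group held 3 arrays, labelled as biological replicates. The labels do not say whether they came from separate mice, so p-values measure the spread between these arrays. The median level per array lay between 4.18 and 4.21 log2 with glutamine and between 4.33 and 4.38 log2 without it. Between 695 and 887 rows per array stood above 16 log2.

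The cultures without glutamine had lost most of the signal of the genes for IL-17A and IL-22, the cytokines that define TH17 cells, and of the lipid desaturase gene Fads2, while the rows of Scd1, another desaturase gene, fell unequally. Il17a fell from 12.75 ± 0.41 to 5.94 ± 0.47 log2 (SD, n = 3), and Il22 fell from 13.53 ± 0.72 to 6.61 ± 0.41. Scd1, which makes monounsaturated fatty acids, fell from 11.59 ± 0.16 to 4.51 ± 0.25 on its brighter row, but another row of Scd1 fell by 2.05. Fads2, which desaturates polyunsaturated fatty acids, fell from 11.18 ± 0.28 to 4.53 ± 0.08. The levels of Scd1 and Fads2 without glutamine lie near the array medians, so the size of their falls may be limited by the floor of the arrays. The other genes among the 10 largest falls were Nrn1 (-6.00), Iltifb (-5.49), Anxa2 (-4.92), Il23r (-4.83), Tgm2 (-4.44) and Lum (-4.37). Iltifb is a near-identical copy of Il22, so its own change is uncertain. Smaller but clear rises ran the other way: Ccl20, the ligand of the chemokine receptor CCR6, rose by 3.28 from 10.24 ± 0.64, and the growth factor gene Fgf2 rose by 3.15 from 7.53 ± 0.17. Anxa3 (2.89), Kctd14 (2.86), Myof (2.68), Antxr2 (2.67), Cox6a2 (2.57), Avil (2.497), Nt5e (2.47) and Gpr83 (2.31) completed the 10 largest rises. The rule took only genes whose groups do not overlap, and the highest adjusted p (limma) among these 20 was 0.00124, that of Tgm2.

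**Figure D1:**
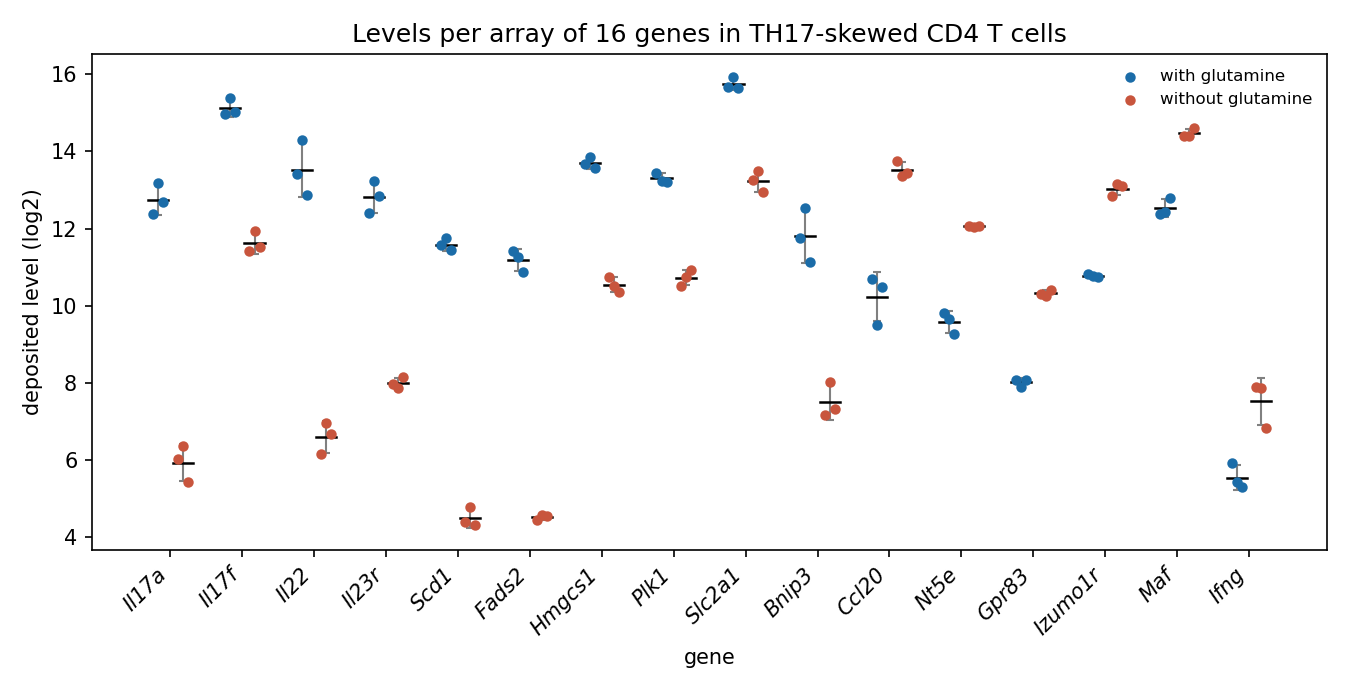
Deposited level (log2, vertical axis) of 16 genes (horizontal axis) on each array with glutamine (blue points) and without it (red points); black lines are group means and grey bars the SD of 3 arrays. The arrays of the groups do not overlap for any gene shown, as in 6842 of the 6843 genes past the threshold. Il17a lies at 12.75 with and 5.94 without glutamine on average, and Nt5e at 9.58 with and 12.06 without.

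Of 30702 genes, 6843 passed the threshold (22.3%): 2855 were higher and 3988 lower without glutamine, so that 41.7% of the calls were rises. By at least 1 log2, 381 genes rose and 872 fell, and by at least 2 log2, 21 rose and 160 fell. The groups did not overlap in 43.8% of all genes, against 10% by chance. The group difference lay along the first principal component, with 70.2% of the variance. The split depended on scaling: after quantile normalization 1453 genes were higher and 5252 lower (21.7% rises), and after centring the arrays on their medians 1215 were higher and 6126 lower (16.6% rises). The median change over all genes was 0.060 as deposited, -0.048 after quantile normalization and -0.095 after centring, and list medians stand against those values. Leaving out with glutamine replicate 2 gave 4344 genes, and leaving out without glutamine replicate 2 or 3 gave 4060 or 4558.

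Among the 41 lists, 25 were lower and 1 was higher without glutamine at the preset correlation, against 21 and 4 after quantile normalization and 19 and 5 after centring. With an estimated correlation camera called 0 lists at an adjusted p under 0.05, and 6 had an unadjusted p under 0.05, while fry, which tests a list against no change and not against other genes, called 27. The lowest adjusted p of camera with an estimated correlation was 0.285, a value that the adjustment gives to many lists alike. Other splits of the same arrays, which mix the groups, called 6 to 20 lists at the preset correlation. They keep part of the difference between the cultures, so those counts do not show what chance alone gives. The counts of members that passed the gene test are given beside each list.

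Within the TH17 list, 8 of 24 measured members rose and 12 fell (8 and 14 adjusted over the list alone), with a median change of -0.49. Il17a and Il22 were joined among the falls by Il23r, the receptor for IL-23, by Il24 (-3.65) and by Il17f, which fell by 3.50 but kept a level of 11.63 ± 0.28. Ccl20, Maf and Ahr rose; Maf and Ahr encode transcription factors that act in TH17 and IL-10-producing cells. Among genes chosen after their values were seen, the chemokine receptor gene Ccr6 fell by 1.81, while Csf2, which encodes GM-CSF, rose by 1.30 and Runx1 by 0.66. The TH17 list shifted down with adjusted p = 0.0196, but adjusted p = 0.285 with an estimated correlation, 0.16 after quantile normalization, 0.412 after centring, 0.369 among genes above the median level, 0.123 on ranks and 0.125 over protein coding genes only. Over its alternatives it ranged from 0.00184, with fry against no change, to 0.412. Of the genes linked to pathogenic TH17 cells, 2 of 16 rose and 13 fell (2 and 14 adjusted over the list alone), with a median change of -1.62 and adjusted p = 2.57e-09, or adjusted p = 0.285 with an estimated correlation. Its largest falls after Il22 and Il23r were Stat4, which fell from 13.37 ± 0.34 to 10.30 ± 0.12, and Il3 (-3.07). Csf2, given above, is also a member of this list and was among the 2 that rose. Of the genes linked to non-pathogenic TH17 cells, 5 of 8 rose and 2 fell (5 and 2 adjusted over the list alone), with a median change of 1.14. Ikzf3 (1.97), Maf (1.93) and Ahr (1.62) rose, Il10 rose by 0.81, and Cd5l fell by 2.53. That list missed the threshold as deposited (adjusted p = 0.0945), passed it after quantile normalization (0.015) and centring (0.00353), and ranged over its alternatives from 0.00184, with fry against no change, to 0.356.

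Genes of regulatory T cells moved in both directions. Of 21 measured Treg list members, 11 rose and 6 fell (13 and 6 adjusted over the list alone), with a median change of 0.39. After quantile normalization 7 rose and 7 fell, and after centring 8 rose and 7 fell, so the excess of rises depended on the scaling. Nt5e, which encodes the adenosine-producing enzyme CD73, rose from 9.58 ± 0.28 to 12.06 ± 0.03, Gpr83 rose from 8.02 ± 0.10 to 10.33 ± 0.08, and Izumo1r, which encodes folate receptor 4, rose by 2.25. Tnfrsf9 fell by 2.41. Among Treg genes chosen after their values were seen, Ikzf2 rose by 1.49 and Tnfrsf18 fell by 1.08. The list missed the threshold as deposited (adjusted p = 0.0583) and passed it after quantile normalization (0.0113), after centring (0.000682), among genes above the median level (0.0234), over protein coding genes only (0.0255), with fry against no change (0.00194) and without without glutamine replicate 1 (0.0349), within a range of 0.000682 to 0.411 over its alternatives. The TGF-beta response list was the list that shifted up, with 8 of 16 members higher and 1 lower (10 and 1 adjusted over the list alone) and a median change of 0.35; after either scaling 5 rose and 1 fell. The signalling genes Smad3 (1.45) and Tgfbr1 (1.36) and the feedback inhibitor gene Pmepa1 (0.92) rose, and Bhlhe40 fell by 1.39 (adjusted p = 0.00219 for the list, adjusted p = 0.285 with an estimated correlation).

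TH1 genes fell more often than they rose, although Ifng itself rose. Of 22 members, 5 rose and 11 fell (6 and 12 adjusted over the list alone), with a median change of -0.47. After quantile normalization 3 rose and 11 fell, and after centring 3 rose and 12 fell. Ifng rose from 5.55 ± 0.33 to 7.53 ± 0.61 (adjusted p = 0.00668, and 0.055 with the unmoderated statistic, within a range of 0.00282 to 0.055), and Tnf, chosen after its values were seen, rose by 1.15. The IL-12 receptor gene Il12rb2 fell from 13.92 ± 0.50 to 11.04 ± 0.47, Cxcr3 fell by 2.21 and Gzmb fell by 2.08. Tbx21, which encodes T-bet, fell by 0.43 (adjusted p = 0.0193), a call that was lost when any array but with glutamine replicate 3 was left out (adjusted p 0.0526 to 0.0682, and 0.00564 to 0.0682 over its alternatives). The TH1 list had adjusted p = 0.00566, and adjusted p = 0.285 with an estimated correlation. It was 0.0881 after centring, 0.0649 among genes above the median level, 0.0933 on ranks and 0.0547 over protein coding genes only, and ranged over its alternatives from 0.00184, with fry against no change, to 0.285. Of 12 TH2 genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone), with a median change of -0.075 (adjusted p = 0.331). The chemokine receptor gene Ccr8 rose by 1.93, and Ccr4 (-2.10) and Il13 (-0.96) fell, as did Il24.

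Genes of naive T cells rose in 7 of 16 cases and fell in 2 (8 and 2 adjusted over the list alone), with a median change of 0.28 that shrank to 0.065 after quantile normalization and 0.13 after centring. The quiescence factor genes Klf2 (1.58), Foxo1 (1.28) and Foxp1 (1.11) rose, and Il7r fell from 12.61 ± 0.30 to 10.00 ± 0.20. The list had adjusted p = 0.0666 as deposited and passed after quantile normalization (0.0149), after centring (0.00353), among genes above the median level (0.0234), over protein coding genes only (0.0331), with fry against no change (0.0272), without with glutamine replicate 2 (0.0403) and without without glutamine replicate 1 (0.0371), within a range of 0.00353 to 0.418. Of 25 genes of the T activation list, 8 rose and 10 fell (8 and 10 adjusted over the list alone), with a median change of -0.23. Nfatc1 (1.30) and Pdcd1 (1.13) rose, and Tnfrsf9 and the costimulatory receptor gene Icos (-1.79) fell. This list had adjusted p = 0.0567 and passed with the mean over rows (0.0476), with trend and robust (0.0499), with fry against no change (0.0321), without with glutamine replicate 1 (0.0345) or 2 (0.0308) and without without glutamine replicate 1 (0.049), within a range of 0.0308 to 0.604. Of 14 CD4 T cell identity genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone), but 2 rose and 4 fell after quantile normalization. Themis, a T cell receptor signalling gene, fell by 3.26 and Thy1 by 0.93, while Zap70 rose by 0.67. The median of that list was 0.14, and -0.019 after centring, its mean was -0.056 and its test pointed up (adjusted p = 0.331).

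**Figure D2:**
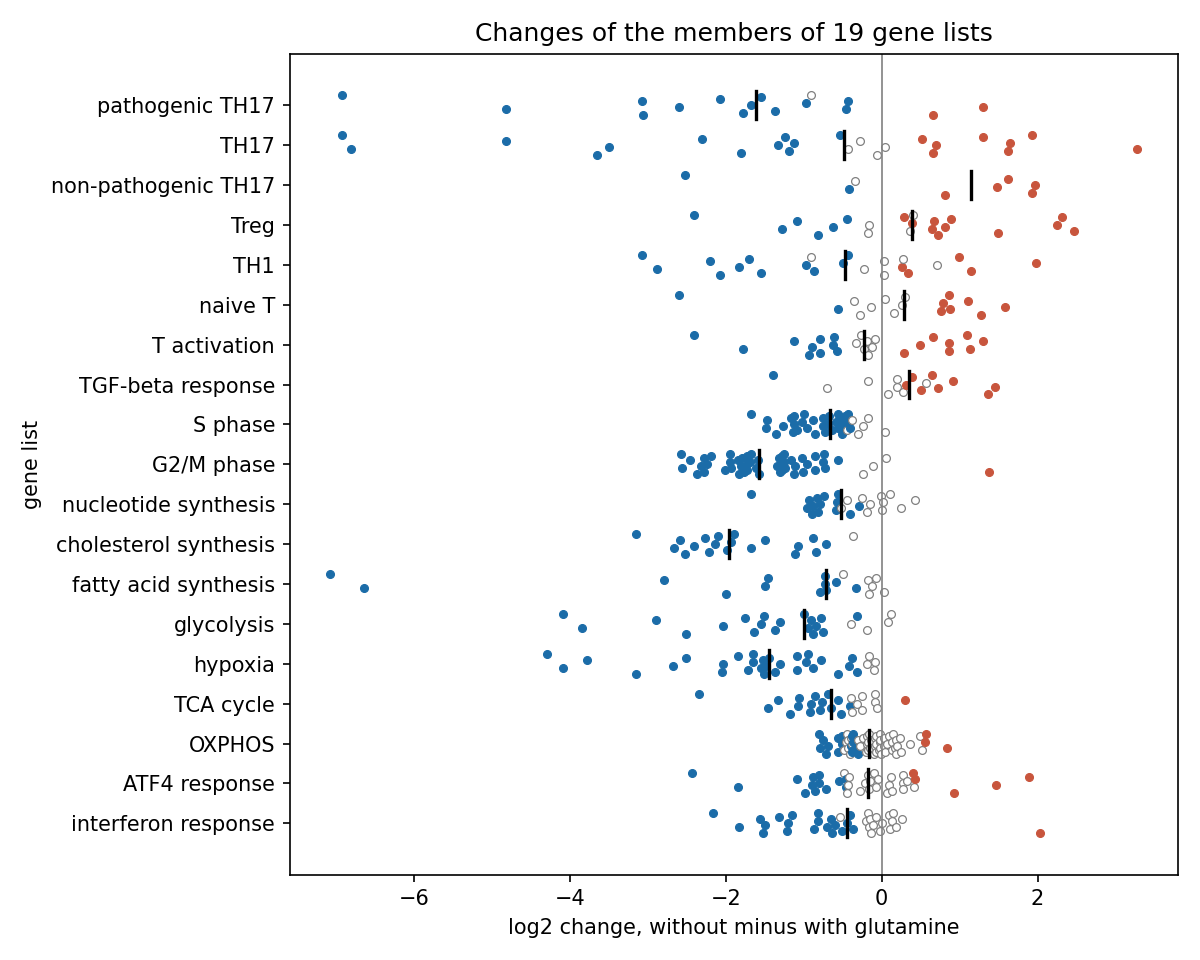
Log2 change of each measured member (horizontal axis, without minus with glutamine) for 19 gene lists (vertical axis); filled points passed the gene test (blue lower, red higher without glutamine), open points did not, and black bars are list medians. The medians run from -1.96 for cholesterol synthesis to 1.14 for the non-pathogenic TH17 list, which lies at 1.05 after quantile normalization and 0.99 after centring.

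Cell cycle genes fell nearly throughout. Of 51 G2/M genes, 47 fell and 1 rose (48 and 1 adjusted over the list alone), with a median change of -1.57. The mitotic kinase genes Plk1 and Aurka fell from 13.30 ± 0.13 to 10.73 ± 0.21 and from 11.82 ± 0.16 to 9.26 ± 0.25, and Cdc20 fell by 2.46. The proliferation marker Mki67 fell by 0.86. The member that rose was Psrc1 (1.38), which also stands in the p53 list. Of 40 S phase genes, 34 fell and the other 6 did not pass (37 fell adjusted over the list alone), with a median change of -0.66. Rrm2, a subunit of ribonucleotide reductase, fell by 1.68, Exo1 by 1.48 and the replication licensing gene Cdc6 by 1.47. Of 25 nucleotide synthesis genes, 14 fell and 11 did not pass (1 rose and 16 fell adjusted over the list alone), with Rrm2, Tyms (-0.96), Atic (-0.93) and Umps (-0.90) as the largest falls. Adjusted p was 5.08e-37 for G2/M, 1.31e-20 for S phase and 3.42e-07 for nucleotide synthesis, and for each of these lists adjusted p = 0.285 with an estimated correlation. Myc changed little, from 14.54 ± 0.11 to 14.45 ± 0.04 (adjusted p = 0.453). Of 43 ribosome biogenesis genes, 1 rose, 6 fell and 36 did not pass (4 fell adjusted over the list alone); 13 fell after quantile normalization and 15 after centring. Utp15 fell by 0.65 and Rrs1 by 0.58. The list had adjusted p = 0.0113, adjusted p = 0.622 with an estimated correlation, and was not called among genes above the median level (0.415), over protein coding genes only (0.119), with fry against no change (0.342), without with glutamine replicate 1 (0.0572) or without without glutamine replicate 3 (0.0622), within a range of 6.15e-05 to 0.622.

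Targets of p53 rose in 9 of 23 cases and fell in 5 (10 and 7 adjusted over the list alone), with a median change of 0.24. After quantile normalization 7 rose and 6 fell, and after centring 6 rose and 7 fell, with a median of 0.087. Zmat3 (1.30) and Trp53inp1 (1.28) rose with Psrc1, and Perp fell by 2.17. The p53 list had adjusted p = 0.315 and passed after centring (0.0356), within a range of 0.0356 to 0.722. Of 24 apoptosis genes, 2 rose and 8 fell (2 and 9 adjusted over the list alone), with a median change of -0.11. Tnfsf10, which encodes the death ligand TRAIL, fell by 0.997, Pmaip1 by 0.85 and Birc2 by 0.82. That list stood at adjusted p = 0.0428, and adjusted p = 0.285 with an estimated correlation. It was not called after quantile normalization (0.0596) or centring (0.0903), among genes above the median level (0.462), over protein coding genes only (0.197), with array weights (0.0525), on ranks (0.0675), without with glutamine replicate 3 (0.0896) or without without glutamine replicate 2 (0.0527) or 3 (0.0667). Its alternatives ranged from 0.00305, with fry against no change, to 0.462.

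Lipid synthesis genes fell together. Of 20 cholesterol synthesis genes, 19 fell and 1 did not pass (20 fell adjusted over the list alone), with a median change of -1.96. Hmgcs1, an early enzyme of the mevalonate pathway, fell from 13.70 ± 0.15 to 10.54 ± 0.20. Insig1 (-2.66), Stard4 (-2.59) and Fdps (-2.52) followed, and Srebf2, the transcription factor gene of the pathway, fell by 0.89; it was chosen after its values were seen. Of 18 fatty acid synthesis genes, 12 fell and 6 did not pass (13 fell adjusted over the list alone), with a median change of -0.72. Elovl6, a fatty acid elongase gene, fell by 2.80, and Fabp5 fell by 2.00 beside the losses of Scd1 and Fads2. Fatty acid oxidation genes also fell, 12 of 19 with 7 that did not pass (14 fell adjusted over the list alone) and a median change of -0.51. The acyl-CoA dehydrogenase genes Acadl (-1.78) and Acadm (-1.68) led, with Hadh (-1.39) and Cpt2 (-1.25). Adjusted p was 2.16e-21 for cholesterol synthesis and 1.13e-10 for fatty acid synthesis, with adjusted p = 0.285 with an estimated correlation for both. For oxidation it was 2.41e-07, and adjusted p = 0.326 with an estimated correlation.

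Genes of glucose use and of the hypoxia response fell without exception among those that passed. Of 23 glycolysis genes, 19 fell and 4 did not pass (20 fell adjusted over the list alone), with a median change of -0.997. The glucose transporter gene Slc2a1 fell from 15.75 ± 0.16 to 13.23 ± 0.28, Slc2a3 fell by 3.85, the lactate transporter gene Slc16a3 by 2.90 and Aldoc by 4.09. Hk2 and Ldha, chosen after their values were seen, fell by 1.55 and 0.94. Of 33 hypoxia genes, 29 fell and 4 did not pass (29 fell adjusted over the list alone), with a median change of -1.45. Bnip3, a mitophagy receptor gene, fell from 11.81 ± 0.70 to 7.51 ± 0.46, Ndrg1 fell by 3.78 and Ak4 by 3.15. Adjusted p was 3.87e-13 for glycolysis and 2.31e-19 for hypoxia, and adjusted p = 0.285 with an estimated correlation for both.

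TCA cycle genes fell in 16 of 25 cases, with 1 rise and 8 that did not pass (17 fell and 1 rose adjusted over the list alone). Idh1, the cytosolic isocitrate dehydrogenase, fell from 8.73 ± 0.44 to 6.39 ± 0.14, and Acly (-1.45), Sdhd (-1.34) and Pdhb (-1.18) fell as well. Of these, Idh1, Acly and Pdhb are enzymes beside the cycle itself that the list also holds, and Acly also stands in the fatty acid synthesis list. The list had a median change of -0.65 and adjusted p = 2.29e-10, or adjusted p = 0.285 with an estimated correlation. Of nuclear genes of oxidative phosphorylation, 3 of 68 rose, 17 fell and 48 did not pass (4 and 23 adjusted over the list alone), with a median change of -0.16; 25 fell after quantile normalization and 28 after centring. The largest change was a rise, of Ndufb11 by 0.84 (adjusted p = 0.0208), a call lost without with glutamine replicate 2 (0.0701) and without without glutamine replicate 1 (0.0662), 2 (0.0586) or 3 (0.0646), within a range of 0.00475 to 0.092. Atp5pb fell by 0.79 and Ndufa4 by 0.76. Their list had adjusted p = 0.000803, adjusted p = 0.583 with an estimated correlation, 0.261 among genes above the median level, 0.22 with fry against no change and 0.0569 without with glutamine replicate 1, within a range of 1.55e-05 to 0.583. None of the 5 measured mitochondrially encoded genes passed limma's threshold, and 1 had an unadjusted p under 0.05. ND3 stood at 18.07 ± 0.16 with and 18.16 ± 0.07 without glutamine and ND2 at 17.78 ± 0.05 and 17.73 ± 0.16. The median of the list was 0.087, and -0.14 after quantile normalization and -0.069 after centring (adjusted p = 0.375).

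Genes that answer amino acid shortage did not move one way. Of 39 members of the ATF4 response list, the programme of amino acid shortage, 5 rose and 13 fell (5 and 17 adjusted over the list alone), with a median change of -0.18. Sesn2, which senses leucine and restrains mTORC1, rose from 10.25 ± 0.09 to 12.13 ± 0.33, Atf5 rose by 1.46 and Ddit3 by 0.93. Vldlr (-2.44), Ero1a (-1.84), the cystine transporter gene Slc7a11 (-0.90) and Chac1 (-0.86) fell. Asns, which encodes asparagine synthetase, stood at 14.31 ± 0.15 with and 13.82 ± 0.24 without glutamine and narrowly missed the threshold (adjusted p = 0.0509). It passed without with glutamine replicate 3 (0.0443) and without without glutamine replicate 1 (0.0322), after quantile normalization (0.0129) and centring (0.0217), among genes above the median level (0.032), with array weights (0.0281) and over protein coding genes only (0.0317), within a range of 0.0129 to 0.147. Trib3 changed by 0.32 (adjusted p = 0.0979), and passed without without glutamine replicate 3 (0.0372), within a range of 0.0372 to 0.376; the glutamine transporter gene Slc1a5 changed by 0.32 (adjusted p = 0.132). The ATF4 response list had adjusted p = 0.0196, and adjusted p = 0.583 with an estimated correlation. It was not called after quantile normalization (0.0913), after centring (0.192), among genes above the median level (0.415), over protein coding genes only (0.153), with fry against no change (0.277) or without without glutamine replicate 2 (0.0513), within a range of 0.00474 to 0.583.

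Of 19 aminoacyl-tRNA synthetase genes, 8 fell and 11 did not pass (11 fell adjusted over the list alone). Cars (-1.01), Kars (-0.80) and Farsa (-0.71) fell (adjusted p = 0.000732 for the list, adjusted p = 0.465 with an estimated correlation). The aminoacyl-tRNA synthetases list was not called among genes above the median level (0.0709) or with fry against no change (0.0627), within a range of 2.4e-05 to 0.465. Of 26 glutamine metabolism genes, 2 rose and 7 fell (3 and 11 adjusted over the list alone), with a median change of -0.090; 10 fell after quantile normalization and 11 after centring, with medians of -0.23 and -0.24. Slc25a13, a mitochondrial aspartate-glutamate carrier gene, fell from 9.64 ± 0.08 to 7.08 ± 0.33, Oat fell by 1.39 and Ppat by 0.81, while Slc38a9, an amino acid sensor of the lysosome, rose by 0.89 (adjusted p = 0.0143 for the list, adjusted p = 0.411 with an estimated correlation). The glutamine metabolism list was not called among genes above the median level (0.117) or over protein coding genes only (0.113), within a range of 0.00303 to 0.411. Of 21 serine and one-carbon genes, 1 rose and 8 fell (2 and 9 adjusted over the list alone). Mthfd1l fell by 1.33, Shmt2 by 0.81 and Psph by 0.80. That list had adjusted p = 0.0196, adjusted p = 0.511 with an estimated correlation, 0.0569 after centring, 0.269 among genes above the median level, 0.125 over protein coding genes only, 0.113 with fry against no change and 0.0667 without without glutamine replicate 3, within a range of 0.00356 to 0.511. Of 11 polyamine and arginine genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone), Smox by 1.30 and Asl by 1.08. The median was 0.10, and -0.10 after quantile normalization and -0.054 after centring, while the mean was -0.12 and the test pointed up (adjusted p = 0.972).

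Redox, chaperone and nutrient-sensing lists leaned downward. Of 28 glutathione and NRF2 genes, 1 rose and 13 fell (1 and 15 adjusted over the list alone). Pgd, an enzyme of the pentose phosphate pathway, fell from 10.80 ± 0.04 to 8.90 ± 0.14, and the thioredoxin system genes Txnrd1 (-1.16) and Txn1 (-1.01) fell (adjusted p = 1.1e-06 for the list, adjusted p = 0.285 with an estimated correlation). Of 22 ER stress genes, 2 rose and 11 fell (2 and 13 adjusted over the list alone), with Sdf2l1 (-1.73) and Pdia6 (-1.04) leading (adjusted p = 0.000149, adjusted p = 0.356 with an estimated correlation). Of 14 heat shock genes, 7 fell and 7 did not pass (8 fell adjusted over the list alone), with Bag3 (-1.42) and Hsph1 (-0.76) leading (adjusted p = 0.00214, adjusted p = 0.326 with an estimated correlation). Among genes above the median level the ER stress list (0.05 after rounding) and the heat shock list (0.0523) missed the threshold, within ranges of 9.88e-05 to 0.356 and 0.000609 to 0.326. Of 28 mTORC1 and nutrient-sensing genes, 5 rose and 10 fell (5 and 12 adjusted over the list alone). After quantile normalization 3 rose and 10 fell, and after centring 2 rose and 13 fell. Sesn2 rose, and Castor1 (-1.80) and Rraga (-1.24) fell. The list had adjusted p = 0.0174, 0.415 among genes above the median level, 0.125 over protein coding genes only, 0.0913 after quantile normalization and 0.0633 after centring, and adjusted p = 0.326 with an estimated correlation, within a range of 0.00889 to 0.415. Of 39 autophagy and lysosome genes, 5 rose and 7 fell (6 and 10 adjusted over the list alone); 3 rose and 12 fell after quantile normalization, and 2 rose and 14 fell after centring. Gabarapl1 (-1.76) and the lysosomal enzyme gene Gla (-1.505) fell, and the list had adjusted p = 0.0981, or 0.0373 without with glutamine replicate 3, within a range of 0.0373 to 0.869.

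In the list of 2-oxoglutarate dioxygenases, which also holds enzymes that make or compete with their substrate, 6 of 27 genes rose and 8 fell (9 and 9 adjusted over the list alone). After quantile normalization 4 rose and 9 fell, and after centring 3 rose and 9 fell. The RNA demethylase gene Alkbh5 fell by 1.24, Jmjd6 fell by 0.89 and the histone demethylase gene Kdm7a rose by 0.84. Idh1, which makes 2-oxoglutarate, fell as given above. The median was 0.12, and -0.034 after centring, the mean was -0.075 and the test pointed down (adjusted p = 0.741). Interferon response genes fell in 20 of 37 cases and rose in 1 (21 and 1 adjusted over the list alone), with a median change of -0.45. The RNA sensor gene Ifih1 fell by 1.84 and Parp9 by 1.57, and the member that rose was Zbp1, from 9.22 ± 0.41 to 11.24 ± 0.16. The list had adjusted p = 1.53e-06, and adjusted p = 0.411 with an estimated correlation.

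Markers of other cell types stayed mostly below the threshold. Of 69 measured markers in 5 lists, 2 rose and 15 fell. Of 12 B cell markers, 1 fell, the transcription factor gene Ebf1 (-2.14; 1 fell adjusted over the list alone). Cd79b, the brightest member after it, stood at 4.40 ± 0.13 and 4.55 ± 0.26. The B cell median was 0.13, and -0.002 after quantile normalization and -0.022 after centring, its mean was -0.075 and its test pointed up (adjusted p = 0.461). Of 20 myeloid markers, 1 rose and 3 fell (1 and 2 adjusted over the list alone). Cd68, a lysosomal protein gene, rose from 7.59 ± 0.15 to 9.16 ± 0.29, and Lyz2 (-1.66) and Ccr2 (-0.83) fell (adjusted p = 0.52 for the list). Of 15 granulocyte markers, 3 fell (3 adjusted over the list alone; adjusted p = 0.184 for the list, with alternatives from 0.00308, with fry against no change, to 0.446). Among NK, CD8 and gamma-delta T markers, 1 of 13 rose and 5 fell (1 and 6 adjusted over the list alone), led by the killer lectin receptor genes Klrc1, which fell from 9.88 ± 0.39 to 6.65 ± 0.25, and Klrd1 (-1.42). That list had adjusted p = 0.035, adjusted p = 0.401 with an estimated correlation, 0.113 on ranks, 0.142 over protein coding genes only and 0.0576 without without glutamine replicate 1. The alternatives for NK, CD8 and gamma-delta T markers ranged from 0.00702, with fry against no change, to 0.401. Of 9 erythroid and platelet markers, 3 fell (1 rose and 3 fell adjusted over the list alone), among them the platelet chemokine genes Ppbp (-3.42) and Pf4 (-2.03; adjusted p = 0.218 for the list, with alternatives from 0.0231, with fry against no change, to 0.446).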

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

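The tests of other cell types, of the share of T cells, of genes shared between lists and of other splits of the arrays were chosen only after the result was seen.

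Rows outside the comparison of named genes also differed between the groups, by amounts that depended on the scaling. Of 33206 rows unnamed here, 4345 were higher and 500 lower without glutamine (limma), with a median change of 0.152, and of 1492 rows naming several genes, 179 were higher and 149 lower. After quantile normalization 2685 unnamed rows were higher and 846 lower (median 0.0429) and after centring 2441 and 956 (median -0.00271), while rows naming several genes turned to 72 higher and 190 lower, and to 53 and 228. A shift of the background between the arrays could account for part of this: 1389 olfactory and vomeronasal receptor genes, which T cells are not known to use, had a median change of 0.104, over the bound of 0.5 times that of the unnamed rows. Unnamed rows matched to protein coding genes on level lay 0.218 above them, but 3444 protein coding genes fell and 1406 rose. The gap mixes that fall with any rise of unnamed rows, so it cannot show whether the level of the rows accounts for the rise. Centring brings the median of all rows near 0, so the median after it says nothing on this. A rise of unnamed transcripts beyond a background shift stays open as a hypothesis.

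The loss of TH17 cytokine transcripts ran beside rises of Nt5e, Gpr83 and Izumo1r, genes that regulatory T cells use, although Tnfrsf9 (-2.41) and, chosen after their values were seen, Ebi3 (-1.27) and Tnfrsf18 (-1.08) of the same list fell, and 7 of its genes rose and 7 fell after quantile normalization. Cells of another lineage in the cultures without glutamine would bring their own abundant transcripts, yet the highest median change of the 5 marker lists was 0.133 and 2 of their 69 genes rose, Cd68 the brighter of them at 9.16 log2. The myeloid and granulocyte lists pool markers of several cell types, so a median alone could miss a single type. The marker lists do not cover other kinds of CD4 T cells. A smaller share of T cells would lower T cell genes as much as Il17a, yet the identity list had a median of 0.136. Regulatory T cells carried over from the start may have contributed, although the sort for CD25-negative cells would remove most; that was not tested, and Foxp3 is not analysed here. A change of the T cells' own programme stays open as a hypothesis.

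The hypoxia list fell although no difference in oxygen is described between the cultures. Genes counted in the glycolysis list as well do not explain it, since 21 of the 24 hypoxia genes outside that list fell, with a median of -1.46. A stronger fall of bright genes does not either: the list median of -1.447 lay below the range of -0.249 to 0.16 that held 95% of 10000 random lists matched on level. A lower density of cells without glutamine, with more oxygen left for each, may be a source, and a direct effect of glutamine on the pathway may be another; neither was tested.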

How the results depend on the processing

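Protein coding genes only and the lists without shared genes were tests chosen after seeing the data. The count of 6843 genes moved most with the threshold and the rows tested. It was 10951 over all rows of the table (6773 higher, 4178 lower), 1253 with a 2-fold change added, 2943 at adjusted p under 0.01, 1284 at unadjusted p under 0.05 with a 2-fold change and 3832 with the unmoderated statistic; the first differs by construction, since more rows were tested, and the 2-fold rule and the threshold of 0.01 are stricter, while the cause was not tested for the others. Leaving out 1 array gave 4060 to 6501 genes with fewer samples, and of the 6843 genes 0 changed sign in any of those fits. For 6842 of them the groups do not overlap, so their sign could not change, and the 0 is no support for the calls. The other 8 settings stayed between 5768 and 7688 genes. The count of 26 lists became 0 with an estimated inter-gene correlation, and 16 among genes above the median level, where 12 lists lost and 2 gained a call; over protein coding genes only 9 lost and 2 gained one; the count was 23 to 28 with 1 array left out and 19 to 27 elsewhere. A higher correlation between genes is not the only source of the loss with an estimated correlation. The estimate was -0.00554 for TH17 and -0.0308 for apoptosis, both under the preset 0.01. Their unadjusted p (camera) still rose from 0.0107 to 0.0473 and from 0.0271 to 0.0704. The cause was not tested for either count.

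Of 183 named genes past the threshold, 182 kept their call after quantile normalization and 181 after centring, and 166 kept it in each fit with 1 array left out. Most named genes were taken for their large changes, so these counts do not describe the other calls. Of all 6843 calls, 5429 were kept after quantile normalization and 5203 after centring. The fits with 1 array left out each kept between 3979 and 5630 of them. With the unmoderated statistic 40 named genes lost their call. Over all alternatives, 247 values of named genes lost their call and 9 gained one, as did 77 and 26 values of lists. Directions reversed where values were near 0, none of them past the threshold, and the cause was not tested. After quantile normalization the change of ND3 was -0.141 and that of Cd79b -0.021, and the list medians were -0.103 for polyamine and arginine and 0.075 for 2-oxoglutarate dioxygenases; after centring these were -0.069, -0.007, -0.054 and -0.034. With 1 array left out the change of ND2 ran from -0.134 to 0.024 and the 2-oxoglutarate median from 0.081 to 0.157, the highest without without glutamine replicate 2, where each reversed. The polyamine test also turned with eBayes with trend and robust (median 0.102), array weights (0.075), fry (0.102) and in 3 fits with 1 array left out (medians over such fits 0.056 to 0.158), the 2-oxoglutarate test among genes above the median level (0.122), on ranks (0.122), and over protein coding genes only (0.122), and the TH2 test with fry (median -0.075).

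The shared replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.066, -0.23 and 0.28 across genes, and 2 of 6 arrays correlated best with their own number. With the replicate block 6292 genes and 25 lists were called, without the apoptosis list.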

Other observations

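Of 23 families of genes defined by their symbols, written before their values were seen, several held more falls or more rises than the reverse, and the members named here were chosen after their values were seen. The patterns of symbols also took in pseudogenes and related genes, such as gamma-tubulin complex genes beside tubulins and Psmc3ip beside proteasome subunits. Of 22 genes of the tubulin family, 13 fell and 9 did not pass, with a median change of -0.54; Tubb6 (-2.99) and Tubb2b (-1.74) fell furthest among those named, though similar tubulin sequences can share probes. Of 42 genes of the proteasome family, 24 fell, with a median of -0.41; Psma1 and Psmd7 fell by 0.89 and 0.88. Among 16 chemokine receptor genes 6 fell and 1 rose, with a median of -0.44: Cxcr4 fell by 3.49 from 9.50 log2, beside Cxcr3, Ccr4 and Ccr6, while Ccr8 rose. Of 80 genes of the mitochondrial ribosomal protein family, 24 fell and 5 rose, with a median of -0.26, and Mrpl45 (-1.18) among the falls. Each of these families shifted down in camera at the preset correlation (adjusted p 1.58e-08 for tubulins, 9.94e-10 for proteasome, 0.00512 for chemokine receptors and 2.76e-07 for mitochondrial ribosomal proteins). With an estimated correlation the tests missed the threshold, with adjusted p = 0.219, 0.412, 0.412 and 0.478.

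Joining segments of the T cell receptor alpha locus rose in 13 of 18 cases and 5 did not pass, with a median change of 1.12, 1.07 after quantile normalization and 0.97 after centring. Traj38 rose by 2.09 to 14.60 log2 and Traj14 by 1.85 to 12.71. Variable segments moved less. Of 88 of the alpha locus 17 rose and 2 fell, with a median of 0.12, and 0.001 after quantile normalization. Of 21 of the beta locus 0 rose and 0 fell, with a median of -0.02. The family of cytosolic ribosomal proteins, which takes in related genes such as Rpl10l, rose in 18 of 37 cases and 19 did not pass, with a median of 0.35 as deposited, 0.21 after quantile normalization and 0.19 after centring. With those scalings 13 and 8 passed as rises. Rps4x rose by 1.08, Rpl37a by 1.06 and Rps10 by 0.74, and pseudogenes of these genes can share their probes. At the preset correlation adjusted p was 2.3e-07 for the joining segments and 1.08e-06 for the ribosomal proteins, and adjusted p = 0.219 and 0.412 with an estimated correlation. The preset test also called the family of 301 vomeronasal receptor genes higher (adjusted p = 0.000941), with 26 rises, although T cells are not known to use them; its median of 0.13 was 0.032 after quantile normalization and -0.024 after centring, and adjusted p = 0.293 with an estimated correlation.

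Against 10000 random lists matched on mean level, 17 of the 41 list medians lay below the central 95%, 6 above and 18 inside. Of the 25 lists called lower, 10 had medians inside it, no lower than chance draws of that level reach: ATF4 response, aminoacyl-tRNA synthetases, glutamine metabolism, OXPHOS, serine and one-carbon, ribosome biogenesis, ER stress, apoptosis, mTORC1 and nutrient sensing, and NK, CD8 and gamma-delta T markers. Treg, non-pathogenic TH17, naive T, TGF-beta response, p53 targets and 2-oxoglutarate dioxygenases lay above it.

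The tests of other splits were chosen after the result was seen. The 6 arrays can be split 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 6843 genes and the highest other 0, with 343 to 1523 genes at an unadjusted p under 0.05 in the others against 11095 in the real one, so 1 of the 10 splits gave as many genes. Each other split mixes the groups, so a difference between the cultures widens the spread inside its parts. Few calls there follow from that difference, and the contrast with 0 is no measure of chance. The real split gave 26 lists and the highest other 20, so 1 of the 10 splits gave as many lists. The other splits also keep part of the difference between the cultures, so their counts of lists do not show what chance alone gives.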
